A study of Mus musculus with 6 samples.

How the data were processed

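The samples were leukaemic cells of 1 line sorted from the bone marrow of 6 mice, 3 in each of 2 groups. Per the labels, the line came from mouse foetal liver cells given a constitutive MLL-AF9 vector with a luciferase, and a doxycycline-inducible FLT3-ITD vector with a DsRED reporter. Groups were taken from the sample titles and treatment labels, which name them ON (doxycycline continued) and OFF (regular food and water for 48 h). All mice were culled at the same time, per the labels' protocols; the markers used to gate leukaemic cells are not given in the sources used here, and a gate on DsRED, which was not analysed here, might have treated OFF and ON cells differently. RNA was isolated with TriZol and a column kit including DNase treatment, and libraries were made with the Lexogen QuantSeq 3' kit, per the labels' protocols. This kit primes near the 3' ends of mRNAs, so a gene's count reflects reads near its annotated 3' end rather than along its length.

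Per the submitters' processing notes, the authors used bcl2fastq 2.17.1.14, FastQC 0.11.6, cutadapt 1.9.1, HISAT2 2.0.4, Subread 1.6.3 with featureCounts, R 3.6.1 and limma 3.42.2, with genome build mm10. Their annotation, strand setting and treatment of reads that map to several places are not given in the sources used here. The authors' deposited table of raw counts held 54838 rows and whole numbers in 6 columns, each matched to a sample by its name. Of these rows, 1105 carried no name; they held between 0.145% and 0.172% of each library's counts and were left out of library sizes and tests. The remaining 53733 rows were named by symbol alone; 235 rows shared a symbol with another row and were kept apart, and 27 symbols had been turned into dates (such as Mar-01) and were not renamed. For 3 list members with several rows the row that came first was used. The authors' second deposited table held log2 values for 12287 genes whose column medians lay within 0.0063 of each other, as after quantile normalisation; its filter and settings are not given in the sources used here, and it was used only as an alternative. Each of its 6 columns correlated best with its own column of counts.

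Total counts were 8810022, 8574853 and 8347588 in ON replicates 1 to 3 and 9329917, 9104450 and 8729496 in OFF replicates 1 to 3. A value of 3 counts, the limit that a count of 0 allows, equals at most 0.36 CPM; PCR reads without molecular identifiers are not independent molecules, so such limits cover counting error only. Rows of the ribosomal RNA locus (CT010467.1, Gm42418 and AY036118) took 12.1%, 11.3% and 16.2% of counts in ON and 18%, 17.2% and 10.1% in OFF. Their counts stood in ratios of 0.98 or more in each library, so the same reads appear in several rows. Mitochondrial rows took between 6.53% and 7.7% of counts. Every pair of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.98 to 9.28 in ON and 6.87 to 39.5 in OFF, so each library was counted as 1 replicate. Of the variance of log2 CPM, a first principal component held 67.6% and parted the groups, and a second held 13.6% and set OFF replicate 3 (-29.3) apart from OFF replicates 1 and 2 (23.9 and 14.4).

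Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with the group as design and its defaults (a minimum count of 10 and a minimum total of 15), which left 13652 rows. Libraries were scaled by TMM, dispersions were estimated robustly, and OFF was compared with ON by glmQLFit and glmQLFTest with no covariate. Log2 fold changes are OFF minus ON, and p-values were adjusted over all tested rows by the Benjamini-Hochberg method at 0.05. The SE of a fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 mice. For a single gene, an exact permutation of 3 against 3 mice cannot give a two-sided p below 0.1, so the adjusted p of the model was used.

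Before the data were examined, 37 gene lists were fixed: serine synthesis and related metabolism, signalling outputs of FLT3, growth, cell cycle, stress, myeloid maturation, MLL-AF9 targets and markers of other bone marrow cells. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for the 35 lists with at least 3 tested members, adjusted over those lists. Camera was repeated with the correlation estimated from the data, and fry was run on the same values; many lists share the adjusted p of 0.212 because the adjustment gives neighbouring ranks the same value. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of that list. The rule for named genes, fixed at the same time, took Flt3, Kmt2a, Mllt3 and the serine synthesis genes; the 6 largest changes in each direction among called genes with a mean of at least 10 CPM and no overlap between groups, leaving out predicted genes; the 3 members with the smallest p in each of up to 10 called lists; the most abundant member of each list of other cells and of the mitochondrial genome list; and the strongest member in the opposite direction of each such list. After the data were seen, the rule for list members was extended to the other called lists, and a few further members were named; these include Shmt2, Tyms, Cth, Asns, Ddit3, Chac1, Etv4, Etv5, Cish, Socs2, Myc, Mki67, Pcna, Cdkn1a, Camp, S100a8, S100a9 and the named monocyte, interferon, MHC class II and pentose phosphate genes. Results of 2 further members are not reported here.

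Positions and gene types came from GENCODE M21 on GRCm38, matched by symbol (97% of symbols and 98.8% of tested ones). Because strand use in counting is not given in the sources used here, reads of overlapping genes on opposite strands may have been counted for either, and rows of near-identical copies and pseudogenes are uncertain. The test was checked on simulated counts with 200 changed genes drawn from the real means and dispersions. In these simulated data, over 13448 genes, it recovered 47.8% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold. Unchanged genes made up between 2.61% and 14.1% of the calls in 5 such draws, which is in most of them more than the nominal 5%. The changed genes were drawn from rows with a mean of at least 20 counts and were far fewer than the 4746 called here. These rates therefore do not measure recovery or false calls in the real comparison. Camera called 0 of 34 lists in simulated data without list effects. Each gene was simulated independently, so this check does not bear on the preset correlation, against estimates of up to 0.63 in the real lists. Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, limma voom, limma on the authors' log2 values, other filters and thresholds, a replicate block, the 20 most abundant genes left out, each library left out, and protein-coding rows only, the last chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.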

Results

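RNA was profiled from a mouse acute myeloid leukaemia line carrying the fusion oncogene MLL-AF9, expressed constantly, and FLT3-ITD, an activated form of the receptor tyrosine kinase FLT3 that is transcribed while doxycycline is present. NSG mice, an immunodeficient strain, received the cells by tail vein and were kept on doxycycline for 96 h of engraftment. Doxycycline was then withdrawn from 3 mice for 48 h (OFF) and continued in 3 mice (ON), after which viable leukaemic cells were sorted from bone marrow and sequenced from the 3' ends of their mRNAs. The 6 libraries, 1 per mouse, held between 8347588 and 9329917 counts, so that 1 count was worth at most 0.12 CPM, the count scaled to the size of its library. The comparison of OFF with ON asks how transcription in the leukaemic cells changes when FLT3-ITD is depleted in the animal, with serine biosynthesis named as the pathway of interest in the series title. The mouse Flt3 gene (GRCm38, chromosome 5, 147330741 to 147400489, minus strand) stood at 5.48, 5.81 and 5.71 CPM in the ON libraries and at 5.44, 5.90 and 9.13 CPM in the OFF libraries (log2 fold change 0.27, SE 0.23, adjusted p = 0.387 by edgeR's quasi-likelihood test). Its row counts the 3' end of the endogenous gene and therefore does not check the depletion of the transgene, whose own reads were not analysed here. Kmt2a and Mllt3, the mouse genes corresponding to the fusion partners, gave log2 fold changes of 0.09 and 0.18 (adjusted p = 0.603 and 0.696).

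After withdrawal, most measured genes of serine synthesis, ATF4 targets, ribosome production and signalling outputs were lower, and the granulocyte, lysosome and FOXO target lists had more members higher than lower. Phgdh, the first enzyme of serine synthesis, fell 4.15-fold, from 93.2 ± 7.31 CPM in ON to 22.4 ± 9.83 CPM in OFF (SD, n = 3 in each group). Cyclin D1 (Ccnd1) fell from 26.4 ± 1.21 to 2.22 ± 0.20 CPM, whereas myeloperoxidase (Mpo) rose from 301 ± 16.4 to 803 ± 138 CPM (SD, n = 3 in each group). Across the transcriptome, 4746 of 13652 tested rows (34.8%) passed an adjusted p of 0.05, 2356 higher and 2390 lower in OFF. Of these, 713 were at least 2-fold higher and 752 at least 2-fold lower. Protein-coding genes made up 3973 of the calls, 2022 higher and 1951 lower. The 3 OFF and 3 ON values did not overlap in 6592 rows (48.3%, against 10% by chance).

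All 3 enzymes of the serine synthesis pathway fell, and all 3 also did so when adjusted over the list alone. The list median was -1.68, and camera gave adjusted p = 0.00219, against adjusted p = 0.212 with an estimated correlation. Phgdh (chromosome 3, 98313170 to 98339990, minus strand) changed by a log2 value of -2.05 (SE 0.24, adjusted p = 1.78e-04), with 33.8, 16.3 and 17.3 CPM in the 3 OFF libraries. Psat1, which makes phosphoserine (chromosome 19, 15904678 to 15947337, minus strand), fell 3.21-fold, from 122 ± 4.67 to 38.0 ± 8.02 CPM (log2 fold change -1.68, SE 0.14, adjusted p = 1.03e-06). Psph, the phosphatase of the last step (chromosome 5, 129765558 to 129787449, minus strand), fell 2.37-fold, from 24.0 ± 3.01 to 10.1 ± 1.08 CPM (log2 fold change -1.25, SE 0.15, adjusted p = 2.48e-05). Its exons share 452 bases with Cct6a on the opposite strand, 21440 bases from the 3' end of Psph, and Cct6a changed by -1.03 (adjusted p = 1.56e-05). Among genes of glycine and one-carbon metabolism, which carries the carbon units released from serine, 11 of 17 measured members fell and none rose (12 adjusted over the list alone). Their median log2 fold change was -0.62 (camera adjusted p = 6.91e-05, and adjusted p = 0.212 with an estimated correlation). The mitochondrial folate enzyme Mthfd2 fell from 131 to 36.7 CPM (log2 fold change -1.83), the glycine cleavage gene Gcsh changed by -1.71, the methionine adenosyltransferase Mat2a by -0.93 and the serine hydroxymethyltransferase Shmt2 by -1.25. Tyms, the thymidylate synthase, did not pass (0.18, adjusted p = 0.198).

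**Figure D1:**
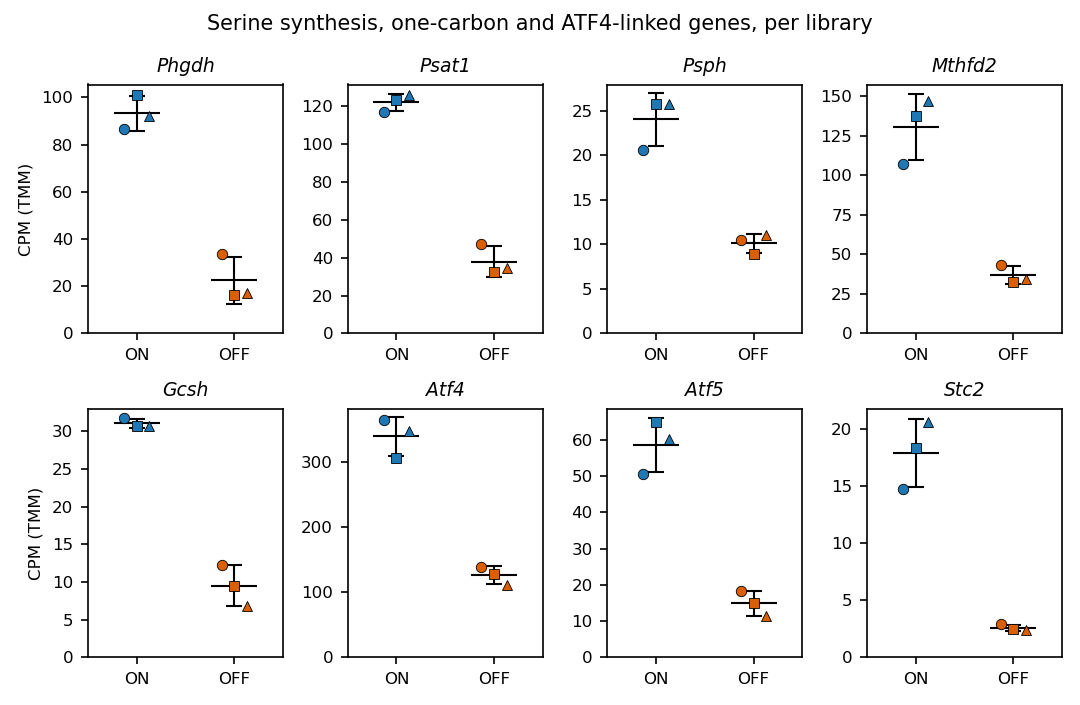
CPM, scaled by TMM factors, of 8 genes in the 3 ON and 3 OFF libraries, where each point is a library (circle, square and triangle for replicates 1, 2 and 3), long bars are group means and error bars are SD. All OFF points lie below all ON points in each panel, for example 16.3 to 33.8 against 86.6 to 101 CPM for Phgdh.

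Targets of ATF4, the transcription factor of the integrated stress response, fell in 18 of 22 measured members and rose in none (19 adjusted over the list alone). The median was -1.36, with a camera adjusted p = 2.52e-10 and adjusted p = 0.212 with an estimated correlation. Atf4 itself fell from 340 to 127 CPM (log2 fold change -1.43, adjusted p = 1.04e-06), Atf5 changed by -1.98 and Stc2 by -2.78. Atf5 shares 82 exonic bases with Nup62 on the opposite strand, which changed by -0.32 (adjusted p = 0.0305, a call lost without any 1 of the ON libraries or OFF replicate 2 and with a replicate block, at 0.0611 to 0.121). The cystathionine gamma-lyase Cth (-3.17) and the asparagine synthetase Asns (-1.30) were also lower. Ddit3 and Chac1, which are tied to the stress response and cell death, gave -0.28 and -0.29 without passing (adjusted p = 0.0898 and 0.516). They were among 4 members that did not pass, whereas Trib3 (-3.85), Nupr1 (-3.44) and Ppp1r15a (-1.94) were among those that fell. Trib3 and Nupr1 were low in OFF, at 0.33 and 0.37 CPM. Of 23 cytosolic aminoacyl-tRNA synthetases and their cofactors, 20 fell and none rose (21 adjusted over the list alone). Camera gave adjusted p = 5.29e-10 for a median of -0.85, and adjusted p = 0.212 with an estimated correlation. Tars changed by -1.31, Gars by -1.39 and Iars by -1.06. Of amino acid transporters, 9 of 17 were lower and 4 higher, the same counts as adjusted over the list alone, and 2 to 4 were higher on leaving out each library in turn. The list median was -0.48, and camera gave adjusted p = 0.00219, or 0.0627 with a minimum of 10 CPM in 3 libraries, against adjusted p = 0.212 with an estimated correlation. Both chains of the large neutral amino acid transporter were among the lower ones, Slc7a5 at -2.86 (33.7 to 4.62 CPM) and Slc3a2 at -1.47, as was the arginine transporter Slc7a1 at -1.51, while Slc7a8 rose by 1.12. Some transporters, Slc3a2 among them, also belong to the ATF4 list. Without those, 7 of 15 transporters were lower and 4 higher, with a median of -0.465. The unfolded protein response list, a stress programme of the endoplasmic reticulum, had 7 of 21 members lower and 1 higher (5 to 9 and 0 to 2 on leaving out each library in turn), unchanged when adjusted over the list alone, and did not pass as a list (adjusted p = 0.052). It passed downwards by fry (adjusted p = 0.00114), with no filter on low counts (0.00911), with protein-coding rows only (0.0435) and without ON replicate 1 (0.0463).

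Outputs of the ERK pathway fell in 13 of 16 measured members and rose in none (13 lower and 1 higher adjusted over the list alone). Their median log2 fold change was -1.60 (camera adjusted p = 1.03e-07, and adjusted p = 0.13 with an estimated correlation). Ccnd1 changed by -3.56 (adjusted p = 2.22e-08), the ERK phosphatase Dusp6 by -2.10 and the pathway inhibitor Spred1 by -2.81, and the transcription factors Etv4 and Etv5 by -3.61 and -3.49. STAT5 targets fell in 10 of 14 members and rose in none, with the same counts adjusted over the list alone. The median was -1.24, with a camera adjusted p = 3.56e-06 and adjusted p = 0.212 with an estimated correlation. These included Ccnd2 at -3.13, the kinase Pim1 at -2.07 (206 to 49.3 CPM), and the feedback inhibitors Cish at -1.19 and Socs2 at -1.49. Genes repressed by PI3K signalling through FOXO factors rose in 12 of 21 members and fell in 2, also when adjusted over the list alone. Each library left out in turn gave 10 to 13 higher and 1 to 2 lower. Camera gave adjusted p = 6.58e-04 for a median of 0.76, and adjusted p = 0.269 with an estimated correlation. Ypel3 rose by 1.77, Trp53inp1 by 1.49 and Klhl24 by 1.35. In the other direction, Klf2 changed by -1.61 (adjusted p = 0.00976), a call lost without OFF replicate 1 or OFF replicate 3 (adjusted p = 0.112 and 0.122) or with no filter on low counts (adjusted p = 0.0734). Early response and dissociation stress genes, which can also mark handling of the cells, moved with the signalling outputs: 14 of 19 were lower in OFF and none higher (15 adjusted over the list alone). The list median was -0.90, and camera gave adjusted p = 5.16e-07, against adjusted p = 0.212 with an estimated correlation. The heat shock genes Hspa1b and Hsph1 changed by -2.02 and -1.55, and Junb by -0.90. Exons of Junb overlap those of Prdx2 on the opposite strand. Their means over the 6 libraries were similar (40.7 and 40.4 CPM), so the Junb row may hold reads of Prdx2. Without the members held by both lists, 11 of 13 ERK outputs were lower, with a median of -1.58. Likewise, 12 of 16 early response and dissociation stress genes outside the ERK list were lower and none higher, with a median of -0.86.

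The MYC target and ribosome biogenesis list was lower in 44 of 45 members and higher in none (45 adjusted over the list alone). Their median log2 fold change was -1.25 (camera adjusted p = 1.9e-21, and adjusted p = 0.212 with an estimated correlation). Myc changed by -1.58, the ribosome assembly factor Rrs1 by -1.59, and the polyamine synthesis genes Srm and Odc1 by -2.09 (104 to 24.5 CPM) and -1.54. Mitochondrial ribosome and mitochondrial stress genes fell in 25 of 36 members and rose in none (30 adjusted over the list alone). The median was -0.46, with a camera adjusted p = 1.8e-09 and adjusted p = 0.212 with an estimated correlation. Hspd1 (485 to 165 CPM, -1.56), Hspe1 (-1.18) and Hspa9 (-1.19) are chaperones of the mitochondrial matrix. Of these, Hspd1 and Hspe1 share 112 exonic bases at their start sites and belong to both lists. In the pentose phosphate and nucleotide synthesis list, 15 of 28 members fell and 5 rose (16 and 6 adjusted over the list alone; 14 to 15 and 3 to 6 on leaving out each library in turn). Camera gave adjusted p = 0.00171 for a median of -0.43, and adjusted p = 0.212 with an estimated correlation. Purine and pyrimidine enzymes were among the lower ones, with Gart at -1.0, Prps1 at -1.07 and Cad at -1.06, whereas the members that rose were the pentose phosphate enzymes G6pdx, Pgls, Pgd and Taldo1 and the thymidine kinase Tk1 (0.63). The call of Pgls was lost without ON replicate 1 or 2 (adjusted p = 0.0757 and 0.0631), and that of G6pdx in 8 of the other settings, including DESeq2 (0.0867).

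The cell cycle lists did not pass the test. Of 41 DNA replication and S phase genes, 3 rose and 4 fell (1 and 2 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.642). Of 39 mitosis and G2/M genes, 1 rose and 2 fell (none adjusted over the list alone), with a median of -0.06 (adjusted p = 0.622). Both counts depended on single libraries: the S phase list gave 5 higher and 6 lower without OFF replicate 3 but 1 in each direction without ON replicate 2 or 3, and the mitosis list 8 in each direction without OFF replicate 3 but none without ON replicate 3. The proliferation marker Mki67 gave 0.06 (adjusted p = 0.817, or a rise of 0.26 at 0.0153 without OFF replicate 3) and Pcna 0.02 (adjusted p = 0.901). Nuclear-encoded oxidative phosphorylation genes fell in 11 of 62 members (10 adjusted over the list alone), and the list did not pass (adjusted p = 0.0686). It passed downwards without OFF replicate 3 (adjusted p = 0.00434), with no filter on low counts (0.00911) and with protein-coding rows only (0.0435). The 15 transcripts of the mitochondrial genome gave 1 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.845), with mt-Rnr2 at -0.02 (adjusted p = 0.937). These counts, too, rested on single libraries, with none in either direction without ON replicate 1 and 3 higher and 2 lower without OFF replicate 1. Glycolysis had 5 of 22 members higher and 8 lower (5 and 9 adjusted over the list alone), and did not pass (adjusted p = 0.363). Fatty acid synthesis had 2 of 13 higher and 4 lower (adjusted p = 0.378), and cholesterol synthesis 3 of 24 higher and 2 lower (adjusted p = 0.81), with the same counts adjusted over the list alone in both. On leaving out each library in turn, these counts ranged over 3 to 5 higher and 6 to 8 lower for glycolysis, 1 to 2 and 3 to 5 for fatty acid synthesis, and 1 to 4 and 2 to 5 for cholesterol synthesis. The cholesterol list had a median of -0.00464 and a mean of 0.0357, of opposite sign. Hypoxia genes had 4 of 18 higher and 6 lower (5 and 6 adjusted over the list alone), without passing (adjusted p = 0.81). The p53 targets had 2 of 19 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.179), with Cdkn1a at -1.47. The p53 list passed downwards with no filter on low counts (adjusted p = 0.0157) and without ON replicate 1 (0.0454).

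**Figure D2:**
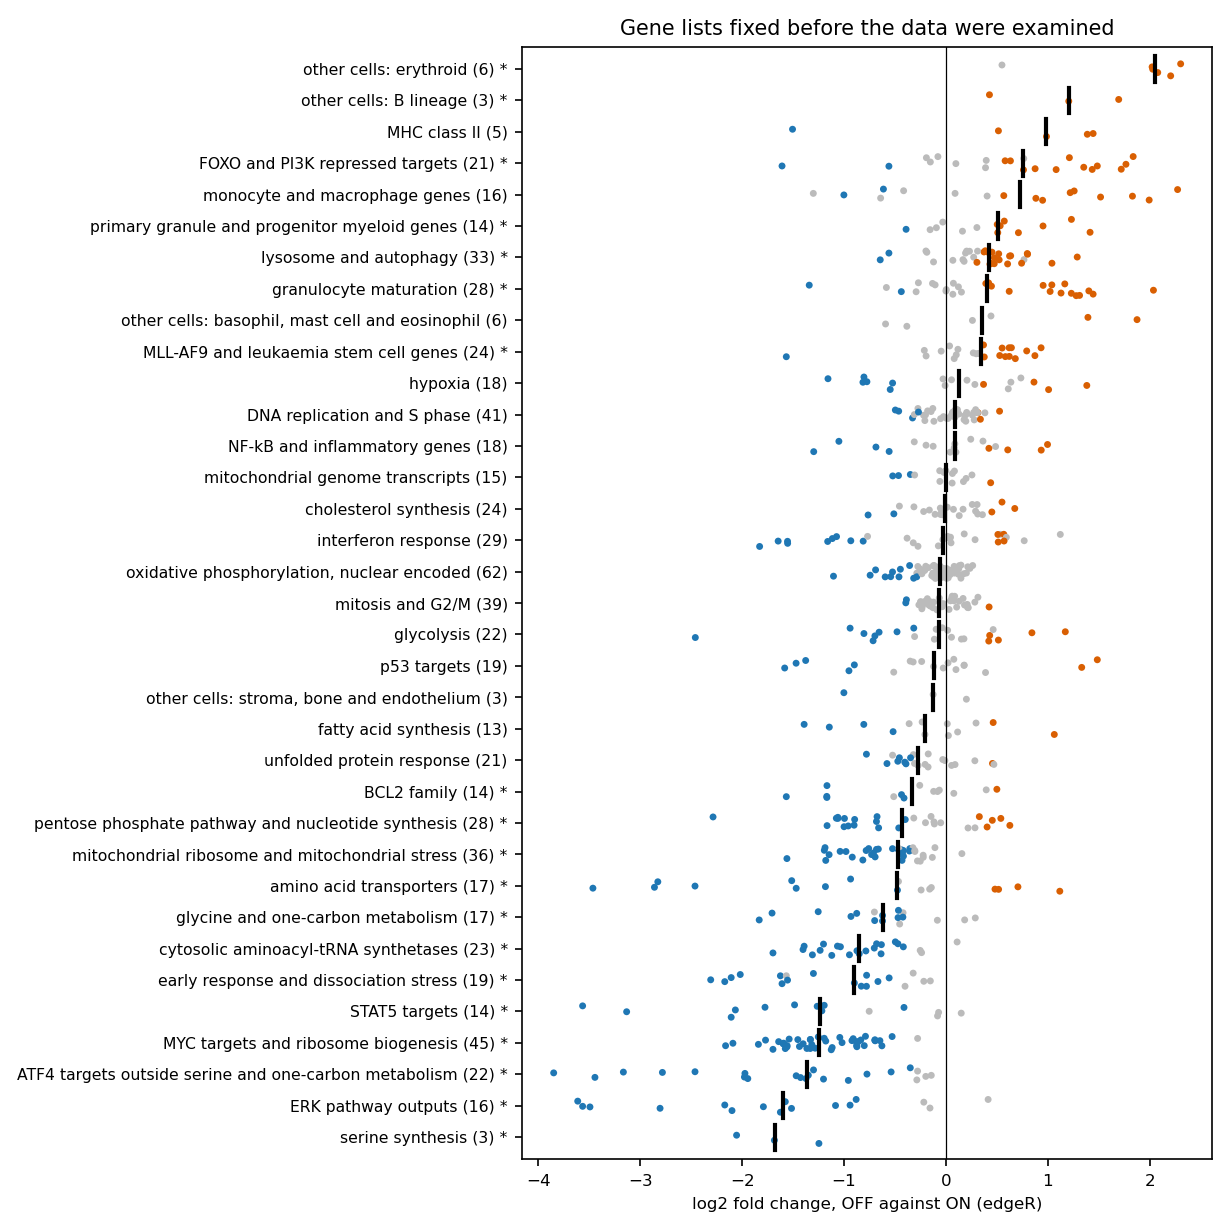
Log2 fold change, OFF against ON, of each measured member of the 35 testable lists (number of members in brackets), ordered by the list median, which is the black bar; orange and blue points passed the gene test upwards and downwards, grey points did not, and an asterisk marks a list past camera. The serine synthesis list has the lowest median (-1.68) and the erythroid marker list the highest (2.05).

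Among myeloid genes, 8 of 14 primary granule and progenitor genes rose and 1 fell, also adjusted over the list alone. The list median was 0.51, and camera gave adjusted p = 0.00724, against adjusted p = 0.212 with an estimated correlation. Mpo rose by a log2 value of 1.42, the lectin Clec12a by 1.23 and neutrophil elastase Elane by 0.95 (840 to 1626 CPM). Ctsg was lower (-0.39, adjusted p = 0.016), a call lost without ON replicate 1, ON replicate 2 or OFF replicate 2 (adjusted p = 0.0555, 0.0797 and 0.0528). Granulocyte maturation genes rose in 15 of 28 members and fell in 2 (15 and 4 adjusted over the list alone). Their median log2 fold change was 0.41 (camera adjusted p = 0.00962, or 0.0864 without OFF replicate 3 and 0.129 by fry, and adjusted p = 0.712 with an estimated correlation). The surface protein Ly6g rose by 2.04, the integrin Itgam by 1.17 and Retnlg by 1.40, while the decoy receptor Il1r2 changed by -1.34. The secondary granule gene Camp stood at 1659, 1560 and 1572 CPM in ON and at 2460, 4068 and 6515 CPM in OFF (log2 fold change 1.44, adjusted p = 0.0135). This call was lost without ON replicate 1 or 3 (adjusted p = 0.0575 and 0.0795) and with no filter on low counts (0.116). The abundant S100a8 and S100a9 gave -0.29 and -0.27 without passing (adjusted p = 0.0608 and 0.0666), but each passed downwards in 4 other settings, such as without OFF replicate 3 (0.00166 and 0.00418). Monocyte and macrophage genes rose in 9 of 16 members and fell in 2, also adjusted over the list alone. With each library left out in turn, 7 to 9 were higher and 1 to 4 lower. The list did not pass (adjusted p = 0.052). It passed in 8 of the other settings, with adjusted p from 0.0129 to 0.044. The lysozyme Lyz2 rose by 2.27, Adgre1 by 2.00 and Ms4a6c by 1.83. Lysosome and autophagy genes rose in 19 of 33 members and fell in 2, also adjusted over the list alone. With each library left out in turn, 14 to 19 were higher and 1 to 2 lower. The main list median was 0.42, with a camera adjusted p = 1.42e-04 and adjusted p = 0.269 with an estimated correlation. The granulin gene Grn rose by 1.04, and Map1lc3b and Psap both by 0.80, while the protease gene Ctsl changed by -0.64.

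Markers of red cells were also higher in the OFF libraries, beside the granulocyte, monocyte and lysosome genes. Of the erythroid list, 6 of 19 members in the count table passed the filter, and 5 of these rose, also adjusted over the list alone. Camera gave adjusted p = 6.63e-05 for a median of 2.05, and adjusted p = 0.212 with an estimated correlation. The summed level of the list went from 186 ± 34.5 to 787 ± 195 CPM (SD, n = 3 in each group). Globin rows held nearly all of this, with Hba-a1 at 70.0 and 296 CPM and Hba-a2 at 69.2 and 282 CPM in ON and OFF. The globin genes Hbb-bs, Hbb-bt and Hba-a2 rose by 2.21, 2.30 and 2.02, and Hba-a1, the most abundant, by 2.08. The 2 Hba rows, and likewise the 2 Hbb rows, belong to similar copies that can share reads. The erythroid counts and camera test took each of these rows as a separate member. B lineage markers rose in all 3 measured members, also adjusted over the list alone. The list median was 1.21, and camera gave adjusted p = 0.0449, against adjusted p = 0.212 with an estimated correlation. Among them, Ighm rose by 1.70. The list call was lost without ON replicate 2 (adjusted p = 0.0518), OFF replicate 1 (0.0854), OFF replicate 2 (0.0616) or OFF replicate 3 (0.0508), and with no filter on low counts (0.152). Bank1 rose by 0.43 (adjusted p = 0.0339), a call lost without any 1 of the ON libraries or OFF replicate 2 (adjusted p from 0.0875 to 0.151). Vpreb1 rose by 1.21 (adjusted p = 0.0497), and its call was lost on leaving out any of the 6 libraries (adjusted p from 0.0686 to 0.216). The Vpreb1 row held only 7, 6 and 2 counts in ON and 13, 12 and 12 in OFF. Its exons overlap those of Top3b (86.3 CPM) on the opposite strand, whose reads it may hold. Neither Bank1 nor Vpreb1 passed by DESeq2 (adjusted p = 0.112 and 0.226), with no filter on low counts (0.0547 and 0.119) or with a replicate block (0.0508 and 0.0619), and Vpreb1 did not with the 20 most abundant genes left out (0.0507). Of megakaryocyte markers 1 was measured, Gp1bb, which rose by 0.71 and also passed adjusted over the list alone. Without OFF replicate 1, 3 were measured, 2 rose and the list passed upwards (adjusted p = 0.0485). No T or NK cell marker was measured above the filter. Basophil, mast cell and eosinophil markers rose in 2 of 6 members, Siglec5 (1.88) and Ear1 (1.39), also adjusted over the list alone (adjusted p = 0.231), with Mcpt8 at 0.26 (adjusted p = 0.361). The call of Ear1 was lost in 5 of the other settings (adjusted p from 0.0509 to 0.0824). Stromal and endothelial markers fell in 1 of 3, also adjusted over the list alone (adjusted p = 0.479). That member, Vcam1 (-1.0), also belongs to the macrophage list.

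**Figure D3:**
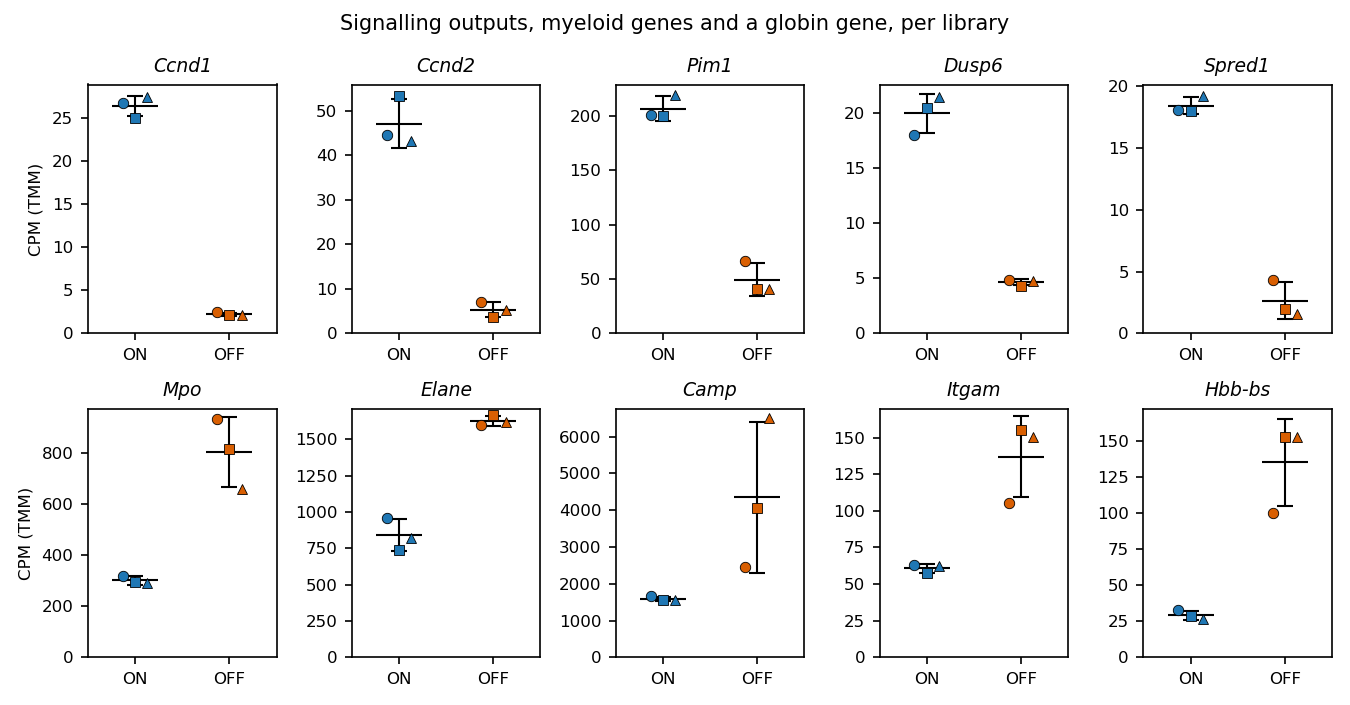
CPM, scaled by TMM factors, of 5 signalling outputs (upper row), 4 myeloid genes and a globin gene (lower row) in the 3 ON and 3 OFF libraries; points are libraries (circle, square and triangle for replicates 1, 2 and 3), long bars are means and error bars are SD. Signalling outputs are lower and the myeloid and globin genes higher in all 3 OFF libraries than in all 3 ON libraries, with Camp spread from 2460 to 6515 CPM in OFF.

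The MLL-AF9 and leukaemia stem cell list was higher in 12 of 24 members and lower in 1 (14 and 1 adjusted over the list alone). Their median log2 fold change was 0.35 (camera adjusted p = 0.00255, and adjusted p = 0.212 with an estimated correlation). Zeb2 rose by 0.93, Hoxa5 by 0.68 and Pbx3 by 0.62, and Meis1 and Myb by 0.37 and 0.53, while Hoxa9 gave 0.08 (adjusted p = 0.543). The call of Meis1 was lost without ON replicate 2, ON replicate 3 or OFF replicate 2 (adjusted p = 0.0579, 0.201 and 0.0812). Bcl2, a survival gene of this list, was the member that fell (-1.57, from 6.59 to 2.22 CPM). The BCL2 family list had 6 of 14 members lower and 1 higher, also adjusted over the list alone (4 to 7 and 1 to 3 on leaving out each library in turn). The median was -0.33, with a camera adjusted p = 0.0184 and adjusted p = 0.212 with an estimated correlation. Its call was lost without ON replicate 3 (adjusted p = 0.0889), without OFF replicate 1 (adjusted p = 0.142) and with a minimum of 10 CPM in 3 libraries (adjusted p = 0.0657). Bcl2a1a, Bcl2a1b and Bcl2a1d each changed by -1.17, but these near-identical copies can share reads and do not count as separate measurements. The list counts and its camera test took each as a member, and the list was not tested again with them as 1. The pro-apoptotic Bad rose by 0.50. Interferon response genes had 4 of 29 members higher and 9 lower (4 and 11 adjusted over the list alone), without passing (adjusted p = 0.326), with Bst2 at -1.65 and Isg15 at -1.55. The list passed downwards without ON replicate 1 (adjusted p = 0.0193) and with no filter on low counts (0.0159), whereas without ON replicate 2 there were 4 higher and 4 lower. MHC class II genes had 4 of 5 members higher and 1 lower, also adjusted over the list alone (adjusted p = 0.052), the lower being Cd74 (-1.51), and passed by fry (0.00417) and with the authors' log2 values (0.008). The call of Cd74 was lost by DESeq2 (adjusted p = 0.113) and without any single library other than OFF replicate 2 (0.0594 to 0.121). NF-kB and inflammatory genes had 4 of 18 members in each direction, also adjusted over the list alone (adjusted p = 0.966). Their median of 0.08 lies above 0, whereas fry gave the direction as down. On leaving out each library in turn, 1 to 4 were higher and 3 to 6 lower, so the even split is not stable.

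The 6 largest rises among genes with a mean of at least 10 CPM and no overlap between groups were in Fcnb, the myeloid lectin ficolin B (3.17, from 24.0 to 216 CPM), Gas7 (2.67, from 4.40 to 28.1 CPM), Ankmy1 (2.45), Gpc1 (2.43), the lysozyme Lyz1 (2.37) and Hbb-bt (2.30). Ankmy1 and Gpc1 overlap tail to tail by 977 bases and their counts stood in a ratio of 0.944 to 1.01 in all 6 libraries, so that their reads cannot be told apart. The 6 largest falls were in the carbonic anhydrase Car4 (-5.81, from 95.9 to 1.70 CPM), Ccnd1 (-3.56), Ccnd2 (-3.13), Slc7a5 (-2.86), Spred1 (-2.81) and Stc2 (-2.78). Car4 stood at 3.33, 1.11 and 0.66 CPM in the OFF libraries.

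Gene calls were made with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and list calls with limma's camera at a preset correlation of 0.01, which called 19 of 35 lists, 12 lower and 7 higher in OFF. With the correlation estimated from the 6 libraries (4 residual degrees of freedom), camera called 0 lists, and 4 had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 21 passed. Removal of doxycycline and loss of FLT3-ITD coincide in this design and cannot be separated by it.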

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

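The comparison restricted to protein-coding rows was chosen after the result was seen; the other alternatives were planned. A stricter adjusted p under 0.01 left 2940 genes, 1424 higher and 1516 lower, and a requirement of at least 2-fold left 1465, 713 higher and 752 lower, because both thresholds keep fewer genes by construction. Of the gene lists, 0 passed with an estimated correlation, and the serine synthesis list then had an adjusted p of 0.212. Leaving out each library in turn gave from 3293 genes (without ON replicate 2) to 5444 (without OFF replicate 1), 1615 to 2704 of them higher and 1678 to 2740 lower, and 18 to 23 lists. The other refits gave 3410 to 5029 genes, and none of the 4746 genes had the opposite sign in any of the 15 refits that tested it. DESeq2 called 3793 genes, 3676 of them in common and in the same direction, and the authors' log2 values with limma 4262, of which 4121 were in common. With protein-coding rows only, 3967 of the 3968 calls tested again were kept. The log2 fold change of Phgdh lay between -2.47 (without OFF replicate 1) and -1.87 (without OFF replicate 2), that of Psat1 between -1.87 and -1.58 and that of Psph between -1.35 and -1.16, and all 3 passed throughout. The monocyte list ranged from an adjusted p of 0.0129 with the stricter filter to 0.123 without OFF replicate 3, and stood at 0.542 with an estimated correlation. The shared replicate numbers do not pair the mice: deviations of same-numbered libraries correlated at r = 0.035, -0.076 and -0.05, and 2 of 6 libraries correlated best with their own number. A replicate block gave 4403 genes, of which 4330 were in common with the main calls, and 19 lists. At this depth, genes that changed 1.5-fold were recovered less often than those that changed 2-fold (47.8% against 92.5% in simulated data).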

Other observations

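The tests of gene families, RNA classes, library scale, doxycycline, the cycling share and library splits were chosen after the result was seen. Those of the globin ratio, the neutrophil stages and OFF replicate 3 concern patterns of the main result. They were not in the plan fixed before the data were examined, but their predictions were written before these tests were run.

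Of 14 gene families outside the fixed lists, picked by symbol, all but the kinesins passed camera in one direction or the other at the preset correlation, and none with an estimated correlation. A pass at the preset correlation thus did not set a family apart from most of the others. All 7 measured subunits of the chaperonin CCT fell (median log2 fold change -0.64; camera adjusted p = 1.38e-04; adjusted p = 0.295 with an estimated correlation). Translation initiation factors fell in 30 of 52 members (median -0.39; camera adjusted p = 2.07e-07; adjusted p = 0.25 with an estimated correlation), mitochondrial import genes in 14 of 24 (median -0.56; camera adjusted p = 7.77e-07; adjusted p = 0.295 with an estimated correlation) and nucleoporins in 15 of 20 (median -0.41; camera adjusted p = 2.66e-05; adjusted p = 0.25 with an estimated correlation). Proteasome subunits fell in 26 of 38 and rose in 1 (median -0.44; camera adjusted p = 1.06e-06; adjusted p = 0.295 with an estimated correlation). Of cytosolic ribosomal protein genes, 5 of 76 were lower, with a median of -0.105 (camera adjusted p = 0.0146; adjusted p = 0.661 with an estimated correlation). In the other direction, 6 of 17 vacuolar ATPase genes rose (camera adjusted p = 0.0258), as did 6 of 11 C-type lectins with 2 lower (0.0369), 6 of 13 integrins with 1 lower (0.0362) and 10 of 45 Rab GTPases (0.0333). Subunits of RNA polymerase I and III fell in 8 of 15 with 1 higher (0.00158), those of RNA polymerase II in 5 of 13 (0.0146), and kinesins did not pass (0.301).

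Core histone genes rose in 37 of 65 members and fell in none (median 0.54; camera adjusted p = 4.14e-09; adjusted p = 0.295 with an estimated correlation), and many of these are near-identical copies that can share reads. By RNA class, 58 of 105 small nucleolar RNA rows were lower and 13 higher (median -1.33), while 34 of 59 small nuclear RNA rows were higher and none lower (median 0.63). Processed pseudogenes were lower in 170 of 1225 rows and higher in 18. A 3' kit that primes on poly(A) is not designed for such RNAs, and their rows can hold reads of host genes or parent genes.

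Erythroid transcripts, nearly all of them globin by CPM, were higher in OFF, with Hba-a1 going from 70.0 ± 14.1 to 296 ± 73.2 CPM. Without any scaling, the list's counts in the lowest OFF library exceeded those in the highest ON library by a log2 ratio of 1.48, while library sizes differed by a log2 ratio of at most 0.197 with or without ribosomal and mitochondrial rows, which argues against normalisation as the whole cause. A candidate explanation is RNA of host red cell precursors in the sorted fraction: the log2 ratio of Hba-a1 to Hbb-bs varied over the 6 libraries with an SD of 0.131 of that of Hbb-bs, as a single source of globins would give, but leukaemic cells that turn on globins together might give the same. Summed levels of other markers, of which few passed the filter, went from 37.1 to 62.5 CPM for megakaryocytes, mostly from Gp1bb alone (34.6 to 56.7 CPM). They went from 19.4 to 33.3 for B lineage, 16.1 to 21.4 for basophil, mast cell and eosinophil, and 54.6 to 35 for stroma (a fall in Vcam1, also a macrophage gene). For T and NK they were 7.05 ± 7.55 and 6.93 ± 6.92 (SD, each mean carried by 1 library). The NSG hosts are immunodeficient, so lymphoid markers need not rise with host cells. A general loss of sort purity was therefore not decided either way. The gate of the sort is not given in the sources used here, and if it used DsRED, the reporter on the inducible vector, OFF cells may have been gated differently from ON cells, which would bear on every value of this comparison.

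Granulocyte maturation genes were higher in OFF, and OFF replicate 3 had the highest Camp. Of the 15 members called higher, 14 remained called without that library, which argues against it as the cause of the single calls, although the list itself then no longer passed (adjusted p = 0.0864), its members called lower went from 2 to 7 and its median from 0.41 to 0.29. Mature host neutrophils in the sorted fraction would raise late neutrophil genes at least as much as secondary granule genes; the medians were 0.23 for 10 late genes and 0.62 for 7 secondary granule genes, a difference of 0.389 (exact permutation p over genes = 0.543, two-sided; genes are not independent replicates). The late genes went both ways, from Retnlg at 1.40 to Il1r2 at -1.34, so host neutrophils and maturation of the leukaemic cells cannot be told apart by this test. Maturation after loss of FLT3-ITD therefore stays a hypothesis.

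The fall of the ribosome biogenesis list (mean -1.21) and of the ATF4 targets was weighed against explanations other than the loss of FLT3-ITD signalling. A smaller share of cycling cells would lower S phase and G2/M genes too. Their 80 members had a mean log2 fold change of 0.00299 (4 higher and 6 lower). The SE over genes was 0.0246, but genes are not independent replicates, so it does not measure the spread between mice. With each library left out in turn, the medians lay between 0.04 and 0.11 for S phase and between -0.10 and 0.004 for G2/M. These values argue against a smaller cycling share as the whole cause. Doxycycline acts on mitochondrial translation and might by itself raise ATF4 targets in the ON mice; the median of -1.36 for that list goes with either cause, and the 2 cannot be told apart because drug and transgene change together. The lower phosphatases, cyclins and STAT5 targets are the changes that loss of a receptor kinase would give, but they were not tested apart from doxycycline either. Cells of the parent line without the inducible vector, on and off doxycycline, would separate these and were not analysed here.

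Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real split, which is the real split itself with 4746 by edgeR. The highest of the other splits gave 0, with 268 at an unadjusted p under 0.05. Those splits mix ON and OFF libraries in each group, which adds the difference between ON and OFF to the spread within groups. Few calls were therefore likely in them, and their 0 does not measure chance. With 10 splits, a share under 0.05 cannot be reached.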
